A study of Mus musculus with 6 samples.

How the data were processed

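Total RNA from adipose tissue of wild-type mice was sequenced in 6 libraries, 3 of creeping fat that formed after repeated cautery injury of the colon and 3 of mesenteric adipose tissue from healthy controls. Per the labels' protocols, RNA was isolated with a mirVana kit, samples with an RNA integrity number of at least 7 went on, and libraries were made with a stranded total RNA kit after ribosomal RNA removal, so transcripts without a poly(A) tail are also measured. Group and replicate number were taken from the sample titles. Nothing in the labels says that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be partly technical.

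The authors deposited 1 table of FPKM values, fragments scaled by gene length and by the library's total of fragments, for 22134 gene symbols in the 6 libraries, with no counts beside them. The build was mm10 per the submitters' processing notes. The aligner, the counting program, the gene annotation and the use of strand in counting were not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and reads shared by near-identical copies (Svs3a and Svs3b, Try4 and Try5, Hba-a1 and Hba-a2, and the histone genes) may have been split in unknown ways, so values of such genes are uncertain. FPKM are relative to the library's total, so a class of transcripts that takes a large share of 1 library lowers the values of all others in it.

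The FPKM values kept the depth. Within a gene, values of different libraries are whole multiples of the value of 1 read, which depends on the gene's length and the library's total. Solving for these gave whole reads, within a tolerance of 0.002 reads, for all 18714 genes above 0 in at least 1 library. The smallest length that gave whole reads was taken from a long range of lengths. For genes with reads in few libraries some length nearly always works, so finding one does not show that their counts are right. The other 3420 genes were at 0 in all 6 libraries. The scale was set from short genes whose RefSeq span matched, 272 of 609 tried, and the estimated library totals lay within 0.00062 of whole numbers. The totals were 36158204, 34934843 and 32837045 reads for creeping fat 1 to 3 and 38867151, 31186018 and 43415696 reads for control 1 to 3. Reads recovered in the table's genes made up 99.57% (control 2) to 99.65% (creeping fat 2) of these totals. The totals may therefore count only reads assigned to genes, not all mapped reads. A floor of 3 reads in a gene of 1 kilobase corresponds to 0.0691 to 0.0962 FPKM, which covers counting error only. On simulated genes, every count was recovered for 279 of 289 genes and for 251 of 255 with at least 50 reads. Count models were not run, since the deposited unit is FPKM; limma's voom on the recovered reads was added as an alternative after the data were seen.

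Before the data were examined, the test, the lists, the rule for named genes and a set of other settings were fixed. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, 12812 in all. Values were transformed to log2(FPKM + 1), and creeping fat was compared with control in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with an intercept and the group as the only terms, lmFit and eBayes with a mean-variance trend, two-sided, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Errors of fold changes are limma's moderated standard errors, and errors of FPKM are SDs over 3 libraries. With 3 libraries against 3, an exact two-sided permutation test of 1 value cannot give a p under 0.1, so none is reported. Because of the added 1, fold changes understate the change of genes with low values.

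Gene lists with at least 5 tested members, 39 of them, were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists, and with camera with an estimated correlation and with fry beside it. Planned lists of mitochondrially encoded mRNAs and of replication-dependent histones matched 0 symbols, since the table uses other names. Both were remade with the table's names, and lists of seminal vesicle, prostate and Hox genes were added, after the data were seen. Adjusted p of these remade and added lists are over those lists alone. The seminal vesicle and prostate lists, with small p, are among them, which can make the adjustment of the others more lenient. A list of skeletal muscle genes had too few tested members for camera, and a list of Y-linked genes served as a check of the animals. Named genes were the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher group had a mean of at least 5 FPKM, up to 2 called members of each list in its main direction with the largest called member the other way, the 2 most abundant members of a list with no call, and a fixed set (Adipoq, Lep, Plin1, Pparg, Ucp1, Col1a1, Acta2, Tgfb1, Ptprc, Tnf, Il6 and Xist). Ucp1 did not pass the expression filter, Xist was not analysed here, and some genes that the rule names are not reported here. Hox genes, mitochondrial genes and LOC118568312 in the closing section were chosen after their values were seen.

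Symbols were matched to RefSeq genes of GRCm38.p6, a patch release of the assembly that mm10 names, for coordinates, which are given 1-based. Of the symbols 21914 were found and 220 were not, 172 of them beginning with LOC. Counts recovered for each pair of libraries were compared, and the chi-square per degree of freedom was at least 70.1 for every pair, so no library was counted as a copy of another.

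The settings fixed beforehand were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 FPKM, rescaling to a common total, median-ratio scaling, quantile normalization, eBayes without trend and robust eBayes, the replicate number as a block, a minimum log2 fold change of 1, and leaving out each library in turn. Settings added after the data were seen were voom, leaving out 38 transcripts of the accessory glands and the pancreas, and leaving out creeping fat 2 and control 2 together. In fits without a library the 12812 tested genes were kept. This was decided after a first run in which the filter was applied again to the remaining libraries.

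The tests were checked on simulated data with the spread of these libraries. Of 200 genes changed among 12812, limma called 47 of 100 changed by 1 and 98 of 100 changed by 2 on the log2 scale with the right sign, and 7 unchanged genes. The median estimate for a change of 2 was 1.96. Camera called all 10 lists shifted by 1 and 0 of 25 lists with no shifted member. In 50 draws with no gene changed, camera called at least 1 list in 11 draws and at most 3 lists in a draw. Genes were drawn independently, so these counts do not show how often camera calls lists whose genes move together. In the real data, other divisions of the 6 libraries into 3 and 3 gave up to 24 called lists. Reads were recovered and figures drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.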

Results

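RNA was sequenced from 6 mouse adipose tissue samples of wild-type animals: 3 samples of creeping fat, the mesenteric fat that extends over the injured bowel, taken after repeated cautery injury of the colon, and 3 samples of mesenteric adipose tissue from healthy controls. Values are FPKM, the fragments of a gene scaled by its length and by the library's total of fragments. The library totals recovered from the FPKM values were 36158204, 34934843 and 32837045 reads in creeping fat 1 to 3 and 38867151, 31186018 and 43415696 reads in control 1 to 3, so the depths of the groups overlapped. Of 22134 genes in the table, 18714 were above 0 in at least 1 library and 12812 were tested. The first principal component held 66.69% of the variance and separated the groups. The second held 19.72% and set control 2 apart, and the third held 7.34% and set creeping fat 2 apart. Correlations of the log2 values between libraries were 0.952 to 0.976 within creeping fat, 0.898 to 0.982 within controls and 0.788 to 0.867 between the groups (Pearson's r across genes, which are not independent replicates).

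The comparison asks how the transcripts of creeping fat differ from those of uninjured mesenteric fat. In creeping fat 28 of 29 genes of the fibrillar matrix, 12 of 21 of matrix proteases and their inhibitors, 13 of 19 of macrophages and 9 of 14 of complement rose. There too 19 of 20 genes of adipocyte identity, 18 of 22 of lipid synthesis and 16 of 20 of fatty acid oxidation fell. Camera called each of these lists with a preset correlation and none of them with an estimated correlation (adjusted p from 0.217 to 0.336). Col1a1, which encodes the main chain of type I collagen, reached 3526 ± 741 FPKM (SD, n = 3) in creeping fat against 97.5 ± 5.38 in controls. Lep, which encodes leptin, stood at 2.46 ± 1.09 FPKM against 124 ± 90.6. The largest rises among the called genes were of genes of the seminal vesicle, and the largest falls of genes of the exocrine pancreas. Seminal vesicle transcripts held 5.47% to 9.71% of the FPKM total in creeping fat and at most 0.0174% in controls, and pancreatic transcripts at most 1.65% and 5.02% to 12.7%, so these shares moved with the group as did each gene group described here. In limma's test, 1198 genes were higher and 872 lower in creeping fat at a Benjamini-Hochberg adjusted p under 0.05, and 746 and 529 of them changed by at least 1 on the log2 scale. At an unadjusted p under 0.05 the counts were 2184 and 1759. The 2 groups did not overlap in 4746 tested genes, or 37% of them. The average over all equal divisions of the libraries is 10%. Genes are not independent, so a single division can lie far from that average, and the 37% is no test against chance. Fold changes are differences of mean log2(FPKM + 1), creeping fat minus control, and understate the change of genes with low values.

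The counts moved by over 1.5 times with each library left out. They were 576 higher and 287 lower without creeping fat 1, 700 and 485 without creeping fat 2, and 639 and 342 without creeping fat 3. They were 784 and 510 without control 1, 2896 and 1857 without control 2, and 626 and 306 without control 3. Without both creeping fat 2 and control 2, an alternative chosen after the data were seen, 2713 genes were higher and 1731 lower.

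**Figure D1:**
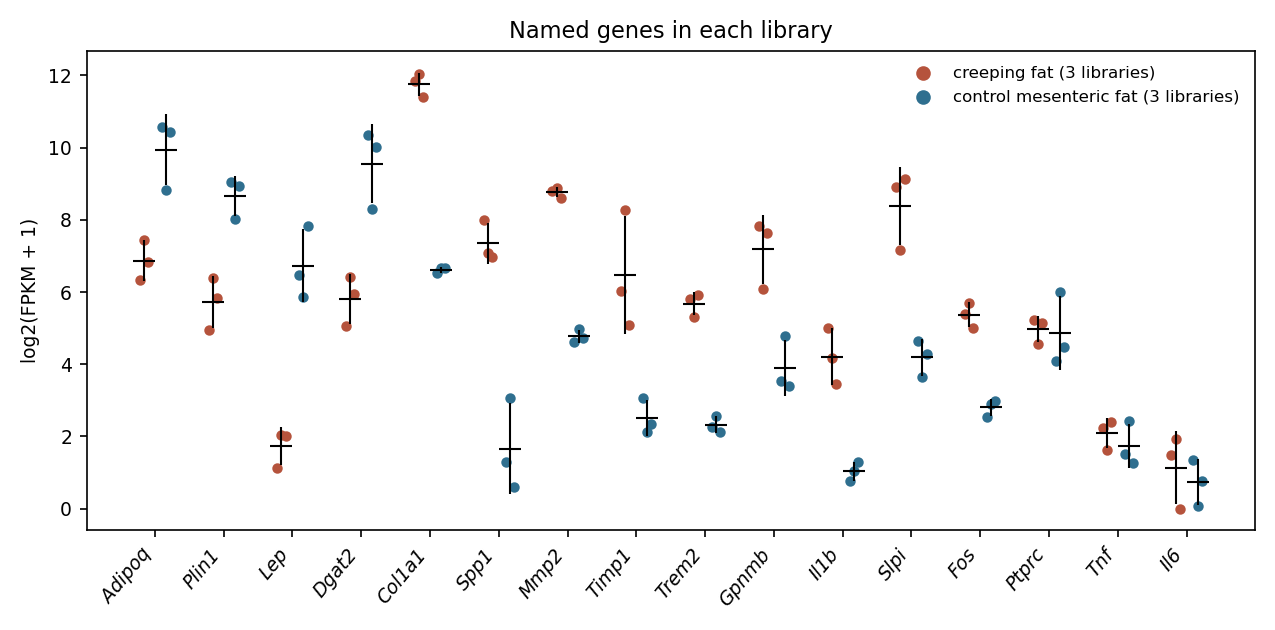
Expression of 16 named genes as log2(FPKM + 1) on the vertical axis, with 1 point per library, 3 creeping fat and 3 control libraries per gene; horizontal marks are means and bars are SDs. Adipoq, Plin1, Lep and Dgat2 lie lower in all 3 creeping fat libraries, Col1a1 to Fos lie higher in all 3, and Ptprc, Tnf and Il6 overlap.

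Adipocyte genes fell together. Of the 20 tested members of the adipocyte identity list, 19 fell and 1 did not pass (20 adjusted over the list alone), with a median log2 fold change of -2.64. Lep fell by 4.99 ± 0.51 (SE; adjusted p = 0.00245), and Adrb3, the beta-3 adrenergic receptor of adipocytes, fell by 3.54 ± 0.44 (adjusted p = 0.0042). Adipoq, which encodes adiponectin, fell by 3.08 ± 0.52 (122 ± 48.0 against 1125 ± 589 FPKM, adjusted p = 0.0105). Plin1, the coat protein of the lipid droplet, fell by 2.95 ± 0.42 (adjusted p = 0.00636), and Pparg, the transcription factor of adipocyte differentiation, fell by 1.79 ± 0.41 (adjusted p = 0.0294). Of 13 tested adipokine genes 7 fell (8 adjusted over the list alone; median -2.06), among them Rbp4, which fell by 3.22 ± 0.59 (adjusted p = 0.0137). Camera called both lists lower (adjusted p = 2.11e-14 and 3.86e-06), but not with an estimated correlation (adjusted p = 0.32 for each). The adipocyte identity list held 0.573%, 1.35% and 0.811% of the FPKM total in creeping fat 1 to 3 against 6.77%, 2.71% and 6.81% in control 1 to 3.

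Most tested genes of lipid synthesis and fatty acid oxidation fell, and few of the respiratory chain and of thermogenic adipocytes did. In the lipogenesis and triglyceride synthesis list 18 of 22 tested genes fell (19 adjusted over the list alone), with a median of -2.76. Dgat2, which catalyses the last step of triglyceride synthesis, fell by 3.75 ± 0.59 (adjusted p = 0.00858), and Me1, the cytosolic malic enzyme that supplies NADPH, fell by 3.65 ± 0.80 (adjusted p = 0.0247). In the fatty acid oxidation list 16 of 20 fell (17 adjusted over the list alone; median -1.16), with Hadh at -1.73 ± 0.32 (adjusted p = 0.0134). In the insulin signalling list 7 of 14 fell (7 fell and 1 rose adjusted over the list alone; median -0.63), with the glucose transporter gene Slc2a4 at -2.57 ± 0.51 (adjusted p = 0.018). Of 84 respiratory chain subunits 5 fell (0 adjusted over the list alone, where 27 fell and 2 rose at an unadjusted p under 0.05 in limma; median -0.52), with Ndufb9 at -0.95 ± 0.25 and Sdha at -0.84 ± 0.22 (adjusted p = 0.0455 and 0.0464). Of 8 tested thermogenic adipocyte genes Ppara alone fell (4 adjusted over the list alone; median -0.52), by 0.96 ± 0.18 (adjusted p = 0.0135). Ppara stood at 0.715 ± 0.299 FPKM in creeping fat and 2.30 ± 0.147 in controls, near the filter of 1 FPKM. Ucp1, the uncoupling protein of brown fat, was under the expression filter, at 0.484 ± 0.714 FPKM in creeping fat and 0.288 ± 0.283 in controls. Camera called these 5 lists lower (adjusted p = 3.68e-12, 1.9e-09, 5.91e-05, 8.13e-09 and 0.0116, in the order given). With an estimated correlation the adjusted p was 0.336 for lipogenesis, 0.632 for the respiratory chain and 0.32 for each of the other lists. Fry did not call the respiratory chain (adjusted p = 0.261). That list held 1.4%, 1.66% and 1.41% of the FPKM total in creeping fat 1 to 3 and 2.6%, 1.5% and 2.34% in control 1 to 3, so control 2 lay among the creeping fat libraries, and its median was -0.85 with creeping fat 2 and control 2 both left out. Without control 2 the thermogenic list was no longer called (median -0.53, adjusted p = 0.0663).

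Matrix genes rose, and the fibrillar matrix list had the highest median of the 39 lists tested. All 29 genes of the fibrillar and interstitial matrix list had positive fold changes, 28 of them rose (28 adjusted over the list alone), and their median was 2.58. Spp1, which encodes osteopontin, rose by 5.68 ± 0.62 (171 ± 71.5 against 3.14 ± 3.73 FPKM, adjusted p = 0.00289), and Col1a1 by 5.14 ± 0.21 (adjusted p = 9.72e-05). The cells that made the Spp1 transcripts were not identified. In GRCm38.p6 coordinates the protein-coding gene Col1a1 lies on chromosome 11 from 94936224 to 94953042, and Spp1 on chromosome 5 from 104435111 to 104441053. The list held 6.23%, 5.83% and 4.29% of the FPKM total in creeping fat and 0.667%, 0.541% and 0.795% in controls. In the matrix protease and inhibitor list 12 of 21 genes rose (17 adjusted over the list alone; median 1.64). Mmp2, which encodes a gelatinase, rose by 4.0 ± 0.16 (adjusted p = 9.72e-05), and Timp1, an inhibitor of such proteases, by 3.95 ± 0.76 (adjusted p = 0.016), with 308.1 FPKM in creeping fat 2 against 64.7 and 33.1 in creeping fat 1 and 3. In the myofibroblast and TGF-beta response list 8 of 18 rose (12 adjusted over the list alone; median 1.18), with the matricellular gene Ccn1 at 2.52 ± 0.41 (adjusted p = 0.00945) and Tgfb3 at 1.94 ± 0.18 (adjusted p = 0.00173). Acta2, the smooth muscle actin of myofibroblasts, did not pass (0.80 ± 0.41, adjusted p = 0.245), nor did Tgfb1 (0.44 ± 0.33, adjusted p = 0.422), which passed without control 2 (0.82, adjusted p = 0.00646). Acta2 stood at 0.47 without control 2 and 1.15 without control 1, and Tgfb1 at 0.24 without control 1. Camera called these 3 lists higher (adjusted p = 8.2e-23, 7.53e-10 and 3.38e-06). With an estimated correlation the adjusted p was 0.32 for the fibrillar matrix, 0.217 for the proteases and 0.32 for the myofibroblast list. None of the 12 basement membrane genes was called by limma on FPKM or by voom on recovered reads (2 at an unadjusted p under 0.05; median 0.21, camera adjusted p = 0.223), and Col4a1 and Nid1 differed by 0.10 ± 0.27 and 0.22 ± 0.29. The basement membrane list was called higher without control 1 (median 0.30, adjusted p = 0.0442) and without control 3 (0.40, adjusted p = 0.0338), and had a median of -0.01 without control 2. The value of Col4a1 was -0.005 after quantile normalization.

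Of the other stromal lists, the adipose progenitor and fibroblast list had 4 of 13 genes higher (5 higher and 1 lower adjusted over the list alone; median 0.49), led by Pi16 at 2.12 ± 0.27 (adjusted p = 0.00426) and Dpt at 1.15 ± 0.22 (adjusted p = 0.0163). Camera called it higher (adjusted p = 0.0282, and 0.32 with an estimated correlation), but not without control 2 (median 0.69, adjusted p = 0.14) or among genes with a mean of at least 5 FPKM (0.46, adjusted p = 0.0755). The progenitor list held 0.459%, 0.401% and 0.505% of the FPKM total in creeping fat 1 to 3. In control 1 to 3 it held 0.56%, 0.348% and 0.593%, so the shares of the groups overlapped. In the blood endothelial list 2 of 12 genes fell (2 adjusted over the list alone; median -0.50), Kdr by 0.86 ± 0.19 (adjusted p = 0.0258) and Robo4 by 0.78 ± 0.18 (adjusted p = 0.0283). Camera called it lower (adjusted p = 0.00484, and 0.32 with an estimated correlation). The lymphatic endothelial list was not called (median 0.01, adjusted p = 0.87), and Pdpn, also expressed by fibroblasts and macrophages, was its 1 gene that rose of 7 (1 adjusted over the list alone; 2.17 ± 0.33, adjusted p = 0.00775). Of 13 mesothelial genes 3 rose (3 adjusted over the list alone; median 0.77, camera adjusted p = 0.235), with Wt1 at 2.00 ± 0.47 (adjusted p = 0.0298) and Krt18 at 1.40 ± 0.37 (adjusted p = 0.0464). Which cells the Wt1 and Krt18 transcripts came from, gland cells included, was not tested. Without control 1 the mesothelial list was called higher (median 0.94, adjusted p = 0.0349), and without control 2 camera placed it lower (median 0.1, adjusted p = 0.698).

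Macrophage genes rose. Of 19 genes on the list, 13 rose and 6 did not pass (15 higher and 1 lower adjusted over the list alone; median 1.77). Trem2, a lipid-sensing receptor of macrophages, rose by 3.36 ± 0.21 (51.2 ± 10.95 against 4.04 ± 0.836 FPKM, adjusted p = 0.000464), and Gpnmb, a gene of lipid-laden macrophages, by 3.28 ± 0.55 (adjusted p = 0.0105). Of 14 complement genes 9 rose and 1 fell (11 and 1 adjusted over the list alone; median 1.27). C3ar1, the receptor of the C3a fragment, rose by 2.58 ± 0.22 (adjusted p = 0.00135), Serping1, which encodes the C1 inhibitor, rose by 1.95 ± 0.18 (adjusted p = 0.00149), and C6 fell by 1.47 ± 0.32 (adjusted p = 0.0236). Camera called both lists higher (adjusted p = 9.45e-08 and 4.33e-06), with an adjusted p of 0.32 for each with an estimated correlation. Ptprc, the common leukocyte antigen CD45, did not pass (0.12 ± 0.49; 31.1 ± 7.28 against 33.6 ± 26.1 FPKM, adjusted p = 0.908), but passed with creeping fat 2 and control 2 both left out (0.90, adjusted p = 0.00723).

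Inflammatory genes rose in part. Of 22 cytokine and chemokine genes 4 rose (8 higher and 1 lower adjusted over the list alone; median 0.48), with Ccl8 at 3.30 ± 0.63 (adjusted p = 0.0155) and Il1b at 3.18 ± 0.38 (adjusted p = 0.00373). Tnf (0.36 ± 0.35, adjusted p = 0.559) and Il6 (0.40 ± 0.54, adjusted p = 0.688) did not pass. With 1 library left out Tnf ranged from 0.12 (without control 3) to 0.70 (without control 2), and Il6 from 0.006 (without creeping fat 2) to 0.97 (without creeping fat 3). With creeping fat 2 and control 2 both left out Tnf passed (0.94, adjusted p = 0.0059), and Il6 stood at -0.32 (adjusted p = 0.614), as it stood at -0.12 by voom. Of 15 genes of microbial sensing 4 rose (6 adjusted over the list alone; median 0.31), with Slpi, a secreted protease inhibitor with antimicrobial activity, at 4.2 ± 0.54 (393 ± 221 against 18.0 ± 6.31 FPKM, adjusted p = 0.0046) and the lipopolysaccharide co-receptor gene Cd14 at 2.16 ± 0.29 (adjusted p = 0.00507). Camera called both lists higher (adjusted p = 0.0128 and 0.0165), with an adjusted p of 0.32 for each with an estimated correlation, and neither was called without control 2 (medians 0.65 and 0.44, adjusted p = 0.125 and 0.0755). The cytokine list was not called among genes with a mean of at least 5 FPKM (0.92, adjusted p = 0.123). The median of the microbial sensing list was 0.52 without creeping fat 2, 0.51 without creeping fat 3 and 0.64 without control 3. Slpi stood at 476.9, 141.6 and 559.5 FPKM in creeping fat 1 to 3. The shares of the prostate and macrophage lists in creeping fat were also lowest in creeping fat 2. Which cells the Slpi transcripts came from, gland cells included, was not tested. Of 12 immediate early genes 6 rose (7 adjusted over the list alone; median 0.90), with Fos at 2.57 ± 0.22 (adjusted p = 0.00133) and Fosb at 2.26 ± 0.31 (adjusted p = 0.0055); camera called the list higher (adjusted p = 4.52e-06, and 0.32 with an estimated correlation). Of 14 interferon response genes Oasl2 rose (1 adjusted over the list alone), by 1.06 ± 0.18 (adjusted p = 0.00999), and the list was not called (median 0.003, from -0.14 without creeping fat 3 to 0.22 without creeping fat 2, mean 0.13, camera adjusted p = 0.519). Of 9 neutrophil genes S100a8 (2.10 ± 0.49, adjusted p = 0.0309) and Il1r2 (2.01 ± 0.34, adjusted p = 0.0106) rose and Elane, a primary granule protease, fell by 0.96 ± 0.17 (adjusted p = 0.0122). Elane stood at 0.297 ± 0.19 FPKM in creeping fat and 1.51 ± 0.12 in controls, near the filter of 1 FPKM. The neutrophil list had 4 higher and 1 lower adjusted over the list alone (median 0.83, camera adjusted p = 0.231). Its median was 0.39 without control 1 and 1.5 without control 2.

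Few lymphocyte genes were called. Control 2 stood apart in them, with 0.136% of its FPKM total in the B cell list against 0.0315% and 0.0408% in control 1 and 3. None of the 11 B cell genes was called by limma or by voom on recovered reads (1 at an unadjusted p under 0.05), and Cd79a and Cd79b differed by -0.48 ± 0.66 and -0.52 ± 0.63. Camera called the list lower (median -0.80, adjusted p = 0.0285, and 0.696 with an estimated correlation), but not without control 2 (median -0.24, adjusted p = 0.196), without creeping fat 2 (median -0.21, adjusted p = 0.227), among genes with a mean of at least 5 FPKM (-0.75, adjusted p = 0.0627) or by fry (adjusted p = 0.429). With creeping fat 2 and control 2 both left out, camera placed the B cell list higher (median 0.226, adjusted p = 0.857). None of the 15 T and NK cell genes passed limma or voom (0 at an unadjusted p under 0.05; median -0.35, camera adjusted p = 0.217), with Ccl5 at -0.35 ± 0.58 and Cd4 at 0.34 ± 0.69. Without control 3 this list was called lower (median -0.70, adjusted p = 0.0256), and without control 2 its median was 0.33 (adjusted p = 0.598). With creeping fat 2 and control 2 both left out Cd4 passed (1.48, adjusted p = 0.00901). The plasma cell list named 13 genes, of which only 6 were in the data. Of these 6 Sdc1, which epithelia and fibroblasts also express, rose (1 adjusted over the list alone), by 2.49 ± 0.18 (adjusted p = 0.00069). Camera called the list higher (median 1.39, adjusted p = 0.0166, and 0.565 with an estimated correlation). Fry did not call it (adjusted p = 0.0514), and the median was 0.90 without control 1. Of 9 lymphoid tissue genes the B cell chemokine gene Cxcl13 rose (1 adjusted over the list alone), by 0.92 ± 0.20 (adjusted p = 0.0248); the list had a median of 0.02, a mean of -0.09 and a camera adjusted p of 0.993. None of the 8 dendritic cell genes (median -0.55, camera adjusted p = 0.407) or the 9 MHC class II genes (median 0.20, adjusted p = 0.96) passed limma or voom (0 of each at an unadjusted p under 0.05). H2-DMb2 and Itgax differed by -0.998 ± 0.60 and 1.38 ± 0.59, and Cd74 and H2-Aa by 0.49 ± 0.48 and 0.61 ± 0.51. Cd74 and H2-Aa stood at 0.058 and 0.067 without control 1 and at 0.96 and 1.06 without control 2. The dendritic cell median was -0.90 without control 1, -0.04 without control 2 and -0.998 among genes with a mean of at least 5 FPKM (adjusted p = 0.118, 0.715 and 0.287), and H2-DMb2 stood at -0.38 without control 2. Without control 2 Itgax passed (1.93, adjusted p = 0.0176). With creeping fat 2 also left out Itgax (2.41, adjusted p = 2e-04) and Cd74 (1.13, adjusted p = 0.039) passed. Of 6 mast cell genes Hdc, the histidine decarboxylase, rose (1 adjusted over the list alone), by 1.202 ± 0.24 (adjusted p = 0.0183), with a list median of -0.04, a mean of 0.21 and a camera adjusted p of 0.678.

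**Figure D2:**
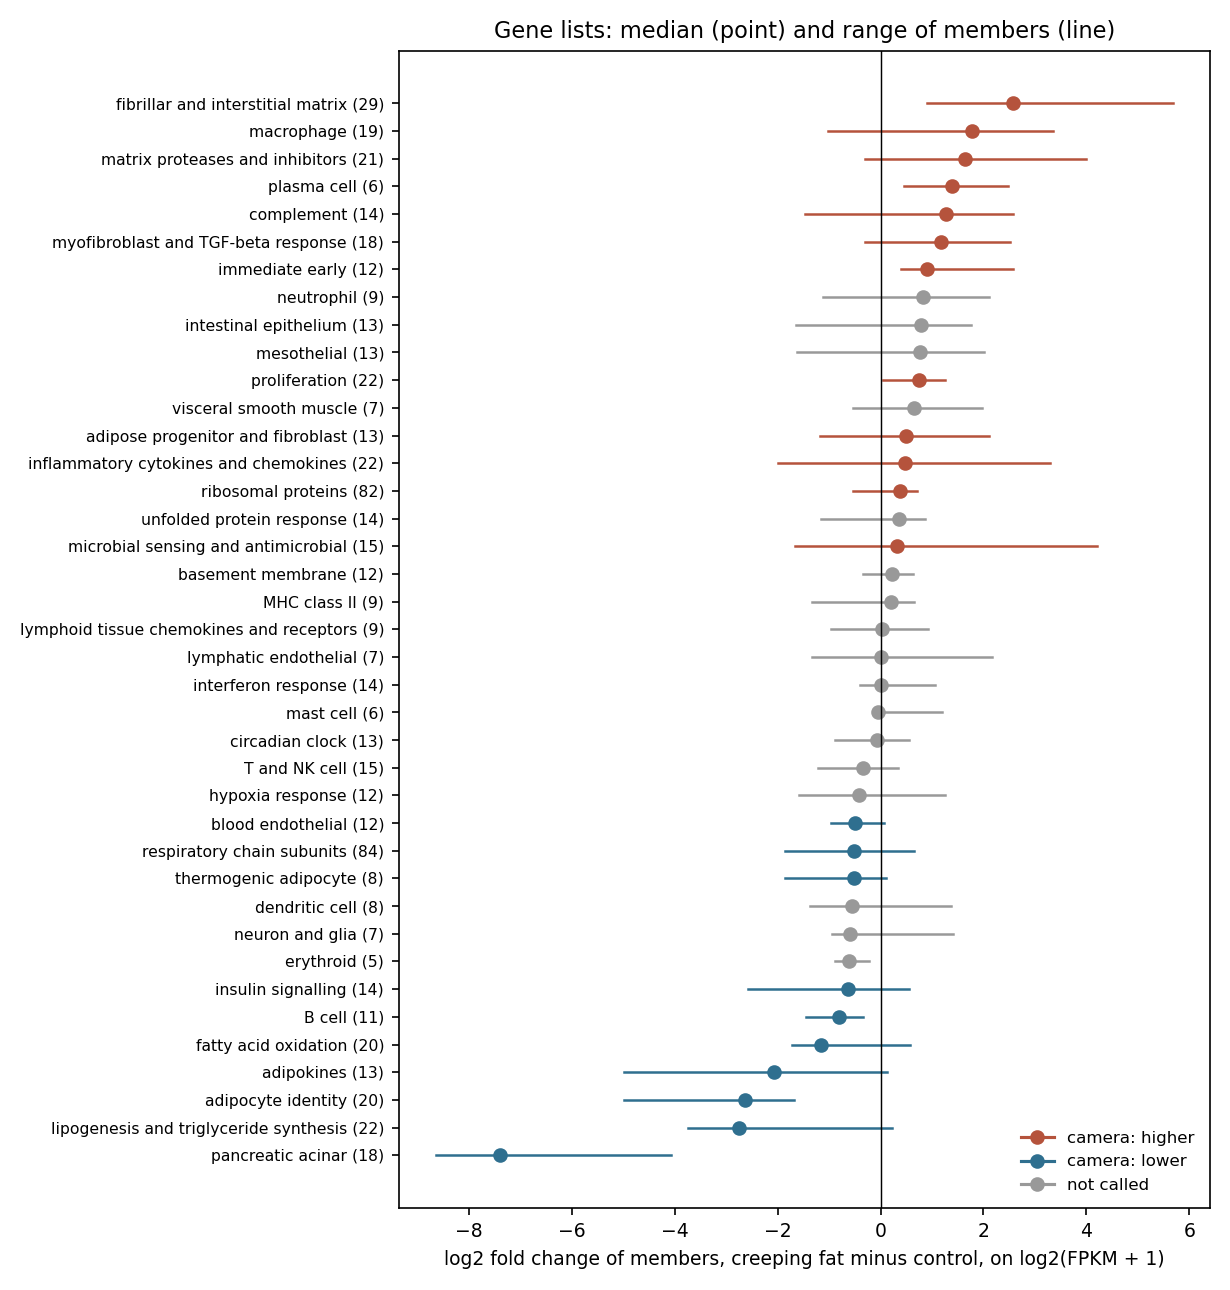
Fold changes of the 39 tested gene lists. The horizontal axis is the log2 fold change, creeping fat minus control, on log2(FPKM + 1); points are list medians, lines run from the lowest to the highest member, numbers of tested members stand in brackets, and colours mark camera's calls with a preset correlation. The fibrillar matrix list has the highest median (2.58) and the pancreatic acinar list the lowest (-7.41).

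Few genes of cell division and protein synthesis were called one by one. All 22 proliferation genes had positive fold changes, with a median of 0.74, and none passed limma or voom (7 at an unadjusted p under 0.05). Mcm7 and Mcm3 differed by 0.053 ± 0.23 and 0.64 ± 0.37, and Mcm3 passed without control 2 (1.06, adjusted p = 0.00403) and stood at 0.32 without control 1. Of 82 ribosomal protein genes 78 had positive fold changes (median 0.39) and Rpl15 rose (0 adjusted over the list alone, where 33 passed at an unadjusted p under 0.05 in limma), by 0.55 ± 0.14 (adjusted p = 0.04). Camera called both lists higher (adjusted p = 0.000403 and 8.04e-10), with adjusted p = 0.637 and 0.49 with an estimated correlation. The proliferation list was not called among genes with a mean of at least 5 FPKM (median 0.67, adjusted p = 0.1) or by fry (adjusted p = 0.261). Its median was 0.45 without control 1 and 1.16 without control 2. Of 14 unfolded protein response genes the chaperone genes Pdia4 (0.87 ± 0.23, adjusted p = 0.0496) and Pdia6 (0.60 ± 0.16, adjusted p = 0.0442) rose (3 higher and 1 lower adjusted over the list alone; median 0.36, camera adjusted p = 0.0971). Of 12 hypoxia response genes 4 fell and 1 rose (5 and 4 adjusted over the list alone; median -0.43, camera adjusted p = 0.369). The hypoxia median was -0.25 without control 2 and -0.74 among genes with a mean of at least 5 FPKM (adjusted p = 0.195 and 0.054). With creeping fat 2 and control 2 both left out, the hypoxia median was -0.115 and the unfolded protein response median 0.607 (camera adjusted p = 0.16 and 0.0713). Pfkfb3 fell by 1.58 ± 0.21 (adjusted p = 0.0051) and Bnip3 by 1.41 ± 0.34 (adjusted p = 0.033), while the glucose transporter gene Slc2a1 rose by 1.25 ± 0.17 (adjusted p = 0.0051). Of 13 clock genes Cry2 fell (0 adjusted over the list alone, where 4 fell and 2 rose at an unadjusted p under 0.05 in limma), by 0.90 ± 0.22 (adjusted p = 0.0335; list median -0.08, camera adjusted p = 0.342).

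Transcripts of other organs differed between the groups. By the naming rule the 10 largest rises were Svs5, Svs4, Svs2, Svs6, Svs1, Pate4, Svs3b, Ceacam10, Svs3a and Pate14, most of them genes of seminal vesicle secretion, with log2 fold changes from 8.73 to 11.07. Svs5, on chromosome 2 from 164332765 to 164334394, stood at 10280 ± 3539 FPKM in creeping fat and 7.82 ± 11.1 in controls (adjusted p = 0.00145). Seminal vesicle transcripts, a list of 13 genes made after the data were seen, held 5.47%, 9.67% and 9.71% of the FPKM total in creeping fat 1 to 3 and 4.71e-05%, 0.0174% and 0.00224% in control 1 to 3, and 7 prostate transcripts, a list made in the same way, held 0.117%, 0.0112% and 0.0865% in creeping fat and at most 0.000292% in controls. The 10 largest falls were Pnlip, Try4, Cela2a, Cpa1, Cela3b, Ctrl, Cpb1, Cel, Clps and 2210010C04Rik, genes of pancreatic digestive enzymes and their cofactors, with log2 fold changes from -8.65 to -6.88. Pnlip, the pancreatic lipase gene, on chromosome 19 from 58670365 to 58681799, stood at 24.6 ± 41.2 FPKM in creeping fat and 2751 ± 1264 in controls (adjusted p = 0.00945). Of 18 pancreatic acinar genes 13 fell (18 adjusted over the list alone; median -7.41), and camera called the list lower (adjusted p = 8.04e-10, and 0.376 with an estimated correlation). The list held 10.2%, 12.7% and 5.02% of the FPKM total in control 1 to 3 and 0.0404%, 1.65% and 0.00763% in creeping fat 1 to 3.

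**Figure D3:**
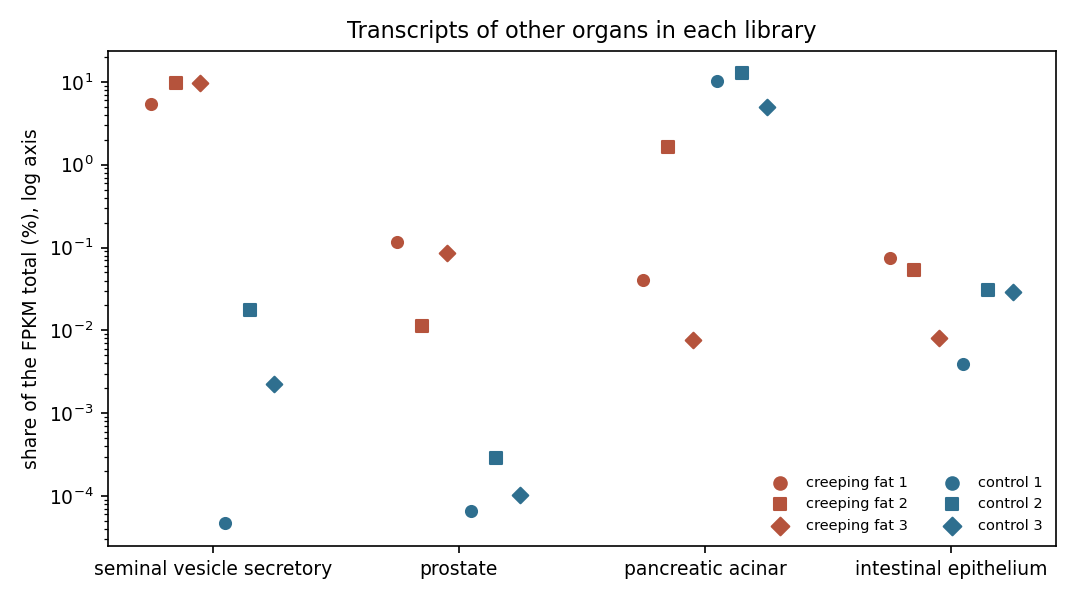
Share of each library's FPKM total, in percent on a log axis, held by 4 lists of genes of other organs, with 1 point per library. Seminal vesicle transcripts hold 5.47% to 9.71% in creeping fat and at most 0.0174% in controls, and pancreatic transcripts 5.02% to 12.7% in controls and at most 1.65% in creeping fat.

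None of the 13 intestinal epithelium genes passed limma or voom (3 at an unadjusted p under 0.05; median 0.80, camera adjusted p = 0.122), with Muc2 at 1.18 ± 1.23 and Tff3 at 1.59 ± 1.26, and the list was called higher without creeping fat 3 (median 1.46, adjusted p = 0.000395). There Muc2 and Tff3 stood at 2.52 and 2.68. Without control 1 the median was 0.30, and Muc2 and Tff3 stood at 0.30 and 0.45. None of the 7 visceral smooth muscle genes passed limma or voom (2 at an unadjusted p under 0.05; median 0.64, camera adjusted p = 0.202), with Actg2 at 1.97 ± 0.81 and Myh11 at 0.71 ± 0.42, and the list was called higher without control 1 (median 0.91, adjusted p = 0.000593), as were Actg2 (2.98, adjusted p = 0.00653) and Myh11 (1.21, adjusted p = 0.0199). Myh11 stood at 0.43 without control 3. In the neuron and glia list 2 of 7 genes fell (3 lower and 1 higher adjusted over the list alone; median -0.60, camera adjusted p = 0.0765), among them Sox10, a transcription factor of Schwann cells, by 0.94 ± 0.21 (adjusted p = 0.0285). Without creeping fat 1 this list and the erythroid list were called lower (medians -0.9 and -1.02, adjusted p = 0.0103 and 0.000326). Without creeping fat 2 their medians were -0.29 and -0.33. With no filter on low values the neuron and glia median was 0.12 (adjusted p = 0.679) and the erythroid list was called lower (-0.47, adjusted p = 0.0311). None of the 5 erythroid genes passed limma or voom (2 at an unadjusted p under 0.05; median -0.61, camera adjusted p = 0.0668), with Hbb-bs at -0.61 ± 0.37 and Hba-a1 at -0.88 ± 0.34. Hba-a1 passed without creeping fat 1 (-1.25, adjusted p = 0.0459), where Hbb-bs stood at -1.02, and without creeping fat 2 they stood at -0.57 and -0.33. Only 3 skeletal muscle genes were tested and the list was not given to camera; Acta1 and Tnni2 differed by 0.16 ± 0.56 and -0.45 ± 0.23. The Y-linked genes Ddx3y (12.2 ± 0.204 against 13.3 ± 1.35 FPKM) and Kdm5d (5.81 ± 0.684 against 5.41 ± 0.845 FPKM) were expressed in all 6 libraries, with fold changes of -0.11 ± 0.13 and 0.090 ± 0.16, and the 4 tested Y-linked genes had a median of -0.049. Xist was not analysed here.

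Of 39 lists tested, camera with a preset correlation of 0.01 called 12 higher and 10 lower, and fry, which asks whether a list's genes move on balance one way, called 17, all of them also called by camera. With an estimated correlation camera called 0 (smallest adjusted p = 0.217; 3 at an unadjusted p under 0.05). Other divisions of the 6 libraries into 3 and 3 gave up to 24 called lists and 0 called genes. Of 75 named genes called, 37 kept an adjusted p under 0.05 whichever library was left out. Calls of named genes ended for 35 without creeping fat 1, 16 without creeping fat 2, 32 without creeping fat 3, 26 without control 1 and 33 without control 3, and for none without control 2, and no called gene changed its direction. Genes that lost the call at least once, with an adjusted p of up to 0.168, included Pparg, Me1, Hadh, Rbp4, Slc2a4, Ppara, Ndufb9, Sdha, Timp1, Dpt, Gpnmb, Ccl8, S100a8, Il1r2, Elane, C6, Cxcl13, Hdc, Kdr, Robo4, Wt1, Krt18, Pdia4, Pdia6, Bnip3, Cry2, Rpl15, Sox10 and each named pancreatic gene except Pnlip.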

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

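Voom on recovered reads, the removal of accessory gland and pancreatic transcripts and the joint removal of creeping fat 2 and control 2 were chosen after the data were seen. The counts of called genes stayed within 1.5 times under both other pseudocounts, both filters, the 3 scalings and both other eBayes settings. They also did so by voom (1196 higher and 872 lower, 1146 and 828 of them shared with the main test). Without 38 listed transcripts of other organs they were 1131 and 861, with 1119 and 827 shared. Other transcripts of gland and pancreatic cells stayed in, so that setting cannot test whether carried-over tissue made the calls. No gene was called the other way in any alternative. Over the pseudocounts, filters, scalings, eBayes settings and the replicate block, 55 calls of named genes were lost, 21 of them with the block; the minimum fold change was applied to the counts only. Of the 22 called lists, 17 were called with any library left out, and 13 also under all other alternatives except the estimated correlation. At 3 libraries per group, limma found 47 of 100 simulated changes of 1 on the log2 scale, so changes of this size can be missed. The simulation changed 200 of 12812 genes, fewer than were called in the data, so the share found in the real test can differ. Except where fewer genes, fewer libraries or fewer degrees of freedom enter by construction, the cause of the changes below was not tested.

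A minimum log2 fold change of 1 left 746 genes higher and 529 lower. With an estimated correlation camera called 0 lists higher and 0 lower, against 12 and 10 (3 at an unadjusted p under 0.05, and 10 and 7 by fry, which did not call the lists of the respiratory chain, B cells, plasma cells, proliferation and the pancreas, with adjusted p from 0.0514 to 0.429). A mean of at least 5 FPKM ended the calls of the adipose progenitor, B cell, inflammatory cytokine and proliferation lists (adjusted p from 0.0627 to 0.123). The list of lymphoid tissue chemokines and receptors, never called, changed camera's direction with a mean of at least 5 FPKM (median -0.675), with no filter (-0.262) and rescaled to a common total (0.057). The proliferation list, called in both, had a median of 1.163 with a pseudocount of 0.1 and 1.281 by voom, against 0.744. Col4a1 stood at -0.005 after quantile normalization and Il6 at -0.124 by voom, neither called.

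With the replicate number as a replicate block, 636 genes were higher and 378 lower, 623 and 369 of them shared with the main test, and the erythroid list was also called lower (median -0.607, adjusted p = 0.0438). The values gave no sign that the numbers pair the samples. Deviations from the group means correlated at -0.181, -0.18 and -0.081 between samples of the same number and at -0.138 to 0.243 between others. No sample correlated best with its own number. With 3 samples per group this cannot exclude a shared batch or cohort.

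Without both creeping fat 2 and control 2, 2713 genes were higher and 1731 lower, 1176 and 857 of them shared with the main test. Fold changes that turned there were those of Acta1 (-0.592), Ccl5 (0.593), Cd79a (0.657), Cd79b (0.564), Col4a1 (-0.232), H2-DMb2 (0.019), Il6 (-0.321) and Nid1 (-0.073), none of them called in either fit. Camera's direction turned for the lists of B cells (median 0.226), T and NK cells (0.488), basement membrane (-0.033), dendritic cells (0.096), mast cells (-0.047), mesothelium (-0.328) and visceral smooth muscle (0.359). Among these, only the B cell list was called in the main test. The lists of adipose progenitors, inflammatory cytokines and microbial sensing were not called there (adjusted p from 0.075 to 0.128).

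With each library left out in turn, the genes higher numbered 576 (without creeping fat 1) to 2896 (without control 2) and the genes lower 287 to 1857 (the same libraries). All 1198 and 872 genes of the main test were among those called without control 2. Fold changes whose sign turned, none of them called in the main test, ranged from -0.202 to 1.066 for Cd4, -0.269 to 0.698 for Ptprc, -0.696 to 0.336 for Ccl5, -0.952 to 0.132 for Cd79a, -1.021 to 0.071 for Cd79b, -0.148 to 0.282 for Col4a1, -0.096 to 0.472 for Nid1, -0.102 to 0.253 for Mcm7, -0.266 to 0.679 for Acta1 and -0.017 to 0.174 for Kdm5d. Lists whose direction by camera turned, none called in the main test, had medians from -0.227 to 0.728 (MHC class II), -0.404 to 0.574 (lymphoid tissue chemokines and receptors), 0.1 to 0.936 (mesothelial), -0.696 to 0.332 (T and NK cell), -0.011 to 0.396 (basement membrane), -0.246 to 0.422 (lymphatic endothelial), -0.311 to 0.349 (mast cell) and -0.247 to 0.012 (circadian clock).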

Other observations

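All tests in this part except the counts over divisions of the libraries were chosen only after the result was seen. Camera's adjusted p for the Hox, mitochondrial and histone lists are over the remade and added lists alone, not over the planned lists. The seminal vesicle and prostate lists are among those, so this adjustment can be lenient. Of 7 tested Hox genes, which mark positions along the body axis, of paralogue groups 10 to 13, Hoxa11 (1.49 ± 0.38, adjusted p = 0.0391), Hoxa13 (1.59 ± 0.26, adjusted p = 0.00935) and Hoxd13 (1.57 ± 0.26, adjusted p = 0.0104) rose in limma's test, and the median was 1.49 (camera adjusted p = 0.00903, and 0.301 with an estimated correlation). Of 11 tested genes of groups 1 to 5, Hoxc5 fell by 1.12 ± 0.21 (adjusted p = 0.0143), and the median was -0.16 (camera adjusted p = 0.0955, and 0.301 with an estimated correlation). The difference between these groups was not tested. Between these groups Hoxc6 and Hoxc8 fell by 1.00 ± 0.16 and 1.97 ± 0.33 and Hoxb8 rose by 0.92 ± 0.22 (adjusted p = 0.00891, 0.0105 and 0.0317).

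Of 13 mitochondrially encoded mRNAs ND3 fell, by 1.16 ± 0.27 (adjusted p = 0.0295), all 13 had negative fold changes (median -1.16), and camera placed the list lower (adjusted p = 0.00015, and 0.301 with an estimated correlation). The list held 2.31%, 2.93% and 2.32% of the FPKM total in creeping fat 1 to 3 and 6.3%, 2.61% and 7.03% in control 1 to 3, so control 2 lay among the creeping fat libraries. Of 57 tested replication-dependent histone genes 3 rose (0 adjusted over the list alone, where 32 passed at an unadjusted p under 0.05 in limma) and 52 had positive fold changes (median 0.96, camera adjusted p = 4.65e-08, and 0.301 with an estimated correlation). LOC118568312 alone held 3.46% of the FPKM total in control 2 and 0.564% to 1.01% in the other libraries.

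The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 2070 called genes and the highest other 0, so 1 of the 10 reached the real count, while up to 1381 genes had an unadjusted p under 0.05 in another division. For gene lists, 5 of the 10 divisions reached the 22 lists of the real one, and the highest other gave 24.

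Male accessory gland transcripts stood in all 3 creeping fat libraries. In controls seminal vesicle transcripts held at most 0.0174% of the FPKM total and prostate transcripts at most 0.000292%. Control animals of the other sex are argued against by the Y-linked genes, whose median log2 fold change was -0.049. Carried-over gland material may account for the pattern: seminal vesicle genes kept 1 ratio between creeping fat libraries (largest SD over genes of the log2 ratio 0.181), while prostate genes followed another (largest difference of the medians 4.138). Tissue taken at different positions along the gut may also have contributed, since the Hox medians of groups 10 to 13 and 1 to 5 differed by 1.651, but accessory glands express posterior Hox genes too, which keeps this open. An effect of the injury itself was not tested.

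Adipocyte transcripts were lower in creeping fat. Dilution by the listed seminal vesicle and prostate transcripts as the whole cause is argued against, since they held at most 3.19% of the recovered reads of a creeping fat library and 83.9% would be needed. Other transcripts of gland cells were not counted. Whether adipocyte transcripts fell by 1 common factor cannot be told apart from a change within adipocytes: after centring each library on the adipocyte identity list, 1 member of that list, Lep, still differed (by -2.15 ± 0.72, adjusted p = 0.00304). The bound was first set over this list and the lipogenesis list together, where 4 of 42 members differed and the bound of at least 3 was met, and it was narrowed after this was seen because Scd2, Fads1 and Fads2, the other 3, are made by many other cells. The centring left 12458 genes called, so its adjusted p is lenient, and a biological change in adipocytes after injury stays open. Tissue taken at different positions along the gut in the groups stays open too and was not tested for these transcripts.

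Matrix transcripts were higher in creeping fat. The values argue only weakly against stroma of the seminal vesicle alone, carried over in proportion to its secretory transcripts. The log2 ratio of creeping fat 2 to 1 was 0.865 higher for seminal vesicle genes than for matrix genes (medians 0.917 and 0.052, SD over matrix genes 0.832). That of creeping fat 3 to 1 was also higher (medians 0.862 and -0.542, SD over matrix genes 0.676). The gap for creeping fat 2 was near the spread of the matrix genes, and both ratios share creeping fat 1. For creeping fat 2 only, the values argue against stroma of the prostate alone, carried over in the same way. The log2 ratio of creeping fat 2 to 1 for prostate genes differed from that of matrix genes by -3.273 (prostate median -3.221). That of creeping fat 3 to 1 (median -0.259) lay within the spread of the matrix genes, so stroma of the prostate stays open for those libraries. Stroma of both glands together or in varying proportion stays open. A lower share of adipocytes alone, which would raise other cell types alike, is argued against by a matrix median 2.575 above the higher of the 2 endothelial medians (pooled SD over members 1.066). A response to the injury, which the design names, may account for the rise and stays open. So do a different mix of stromal cells and tissue taken at different positions along the gut. None of these was tested.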
